A study of Drosophila melanogaster with 2 samples.

How the data were processed

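The samples were 2 biological replicates of whole Drosophila melanogaster pupae aged 24 hours, from a line with a GFP-tagged CG17806, sonicated and precipitated with an antibody against GFP, per the labels' protocols. They form 1 group, and each replicate was called on its own by the authors. Per the file descriptions deposited with the samples, the list of each replicate was made from 1 alignment of that replicate and a control alignment, a pooled list from the alignments of both replicates and the control, and a list thresholded on the irreproducible discovery rate (IDR) from the lists of the replicates and the pooled list. All are on dm6. The aligner, the peak caller and the depth are not given in the sources used here, and the control reads and the signal tracks were not used here.

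The deposited lists give for each peak an interval, a summit, a signal and a q-value as −log10 q. The signal per peak is the authors' own on a scale that is not stated, so it was used only to rank peaks within a list. The deposited −log10 q-value reaches a ceiling that all IDR peaks share, so it could not rank them. In the other lists it goes down to 0.735 in replicate 1, 0.146 in replicate 2 and 0.405 in the pooled list. These lists thus include peaks with a q-value above 0.05. The other value used, the deposited summit offset in bp from the interval start, gave the position of each peak. The 7645 IDR peaks were the 7645 pooled peaks of highest signal, matched on position and on signal to 6 decimals. The commonest width was 376 bp in replicate 1 (75.9% of peaks) and 340 bp in replicate 2 (90.3%), and no summits within a list were closer than 199 bp. No column of per-sample values was left unassigned.

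Genes and start sites came from Ensembl release 115 and the sequence from the Release 6 assembly, whose arms 2L, 2R, 3L, 3R, 4 and X held every peak. A promoter was the sequence within 500 bp of a start site of any gene; a gene was bound when an IDR summit lay within 500 bp of one of its start sites. Summits elsewhere were assigned to 5' UTR, 3' UTR, coding exon, other exon, intron or intergenic, in that order. The tests, 25 gene lists, 18 motifs, the rule for naming genes and most alternative settings were fixed before the data were examined. Some names on the gene lists matched no current symbol and were left out.

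Agreement between replicates was the share of top peaks with a summit of the other replicate within 100 bp, against 1000 circular rotations along each arm (permutation test, one-sided). Location was tested against 1000 random placements on the same arm outside runs of N (two-sided), arms by exact binomial tests on length, promoter rank by 100000 resamples, gene lists by Fisher's exact test against all other protein-coding genes, and small RNA genes by 1000 rotations. Motifs within 50 bp of the summit were compared with a pair of flanks of the same total length centred 250 bp to each side by an exact sign test. Words of 7 bases were ranked on chromosome 2 and tested on the other chromosomes. Benjamini-Hochberg adjustment covered the 7 classes, 6 arms, 25 lists, 18 motifs, 8192 words or 4 kinds of small RNA gene. Intervals of shares are Wilson 95% intervals and those of observed to expected ratios exact Poisson intervals; both cover counting error only, and neighbouring peaks are not independent.

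The genes named are those whose start site is nearest to the 20 IDR peaks of highest signal, the CG17806 locus, for each list that passed the test the 4 bound members of highest signal and the first 2 unbound members by alphabet, and for the other lists up to 2 bound members of highest signal. The words named are the top 3 of chromosome 2.

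Alternatives were other distances for shared and bound, the 1911 strongest IDR peaks, the pooled list, rotation in place of random placement, nearest start sites only, words of 6 and 8 bases, and the top 7645 peaks of 1 replicate in place of the IDR list. Chosen after seeing that summits are AT-rich were placement matched on the AT content of centre and flanks, a logistic model of bound genes with promoter AT content and number of start site clusters, and a comparison of motifs and words with 20 windows per peak, matched on AT content and annotation class and over 500 bp from any pooled peak. A single window per peak was tried first and gave calls that moved from draw to draw, so 20 were used after this was seen. For overlap of intervals, 50 rotations were run. A logistic fit was not made for the Hox list, which has no bound gene. The test of the CG17806 locus against windows of like expectation replaced a Poisson interval after the result of that interval was seen. Gene lists were also tested, as an addition after seeing the data, without chromosome 4 and genes within 2 Mb of a centromeric end.

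The tests of location, gene lists, motifs and words, agreement, promoter rank and small RNA genes were tested on simulated data, and the test of chromosome arms was not. Of 2257 simulated promoter peaks 2257 were found. In a list of 32 genes, 23 were given a peak or already lay near a random one, and 23 were counted as bound. Both counts follow from the construction, so they check the counting and not the power of the tests. In 5337 of 7645 simulated peaks a partner was planted and 5367 were found. A planted word was put in 382 of 7645 windows and seen in 425, which includes chance occurrences. A planted rank shift was called in 40 of 40 runs, and 2 of 40 runs with random ranks passed 0.05. With summits put at 120 of 290 tRNA genes, 180 had one nearby. Without a planted signal, none of the 7 classes, 25 lists, 18 motifs or 4 small RNA classes was called. The simulated peaks were placed at random along the arms, while real summits cluster, so error rates for clustered peaks were not checked. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.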

Results

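The data were chromatin immunoprecipitation and sequencing (ChIP-seq) peak lists from whole fruit fly pupae aged 24 hours. The animals came from a transgenic Drosophila melanogaster line that carries CG17806 with green fluorescent protein at its C-terminal end, and the tagged protein was precipitated with an antibody against that tag. CG17806 (FBgn0038548) lies on the minus strand of chromosome arm 3R from 17801542 to 17803260 in dm6, the build of all coordinates given here. The labels give 1 group with 2 biological replicates, so the replicates could be compared with each other and the peaks with the genome, but no condition could be compared with another. The list of each replicate held 30000 peaks, as did the list called on both replicates together, and the list thresholded on the irreproducible discovery rate (IDR) held 7645 peaks. Read depth is unknown, since the lists hold no read counts. Peak signals are the authors' own and serve only to rank peaks within a list.

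The 20 IDR peaks with the highest signal all had a summit within 100 bp in both replicate lists, and all ranked among the top 100 there. Much of this follows from how the list was made, since the IDR peaks are those of highest signal in the list called on both replicates together. The first of them lay at 3L from 19590405 to 19590815, with its summit 88 bp upstream of the start site of CG14100 (FBgn0036889). The peak at X from 2703673 to 2704103 had its summit 29 bp upstream of Ugalt, which encodes a UDP-galactose transporter. Those at 2R from 15217551 to 15217983 and at 3R from 15229342 to 15229735 lay upstream of mRpL41 and mRpS10, which encode proteins of the mitochondrial ribosome. The peak at 3L from 9383628 to 9384144 had its summit 149 bp upstream of the small heat shock gene Hsp27.

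Of the 20, 13 were at promoters, 4 in introns, 2 in exons of non-coding RNAs and 1 between genes. The other promoter peaks were nearest to the start sites of CG18549, lncRNA:CR44619, PNPase, CenG1A, Chro, larp, Tcs5 and CG5611. PNPase is a mitochondrial RNA-degrading enzyme and Chro a chromodomain protein of chromosomes and the spindle. The intronic peaks were nearest to the start sites of CG11050, cbt, CG32772 and Lk6, and the one nearest to cbt lay in an intron of ush at 2L from 480851 to 481324. A second peak at lncRNA:CR44619 and one at lncRNA:CR46035 fell in exons of these non-coding RNAs. The intergenic peak, at 2L from 2202159 to 2202695, was 3760 bp from the nearest start site, that of CG31668.

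Of the 7645 strongest peaks of replicate 1, 5689 had one of the 7645 strongest summits of replicate 2 within 100 bp. That is 74.4% (Wilson 95% interval 73.4 to 75.4), against a mean of 1.16% and a highest value of 1.79% over 1000 circular rotations of one list. The one-sided permutation p was 0.000999, the smallest that 1000 rotations can give. Over all peaks of both lists the share was 43.5%. Agreement fell with rank: 97.8% of the first 3000 peaks of replicate 1 had a partner anywhere in the list of replicate 2, against 11.4% of the last 3000. The lists of replicates 1 and 2 go down to a −log10 q of 0.735 and 0.146, so they include calls with little support. Across the 13049 matched peaks, signal ranks correlated with a Spearman rho of 0.839. This is a correlation across peaks, which are not independent replicates. Of the IDR peaks, 7056 (92.3%) had a summit within 100 bp in both replicate lists and 13 in neither. The IDR list was made from these lists and the pooled list, so this share is not further evidence of agreement.

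**Figure D1:**
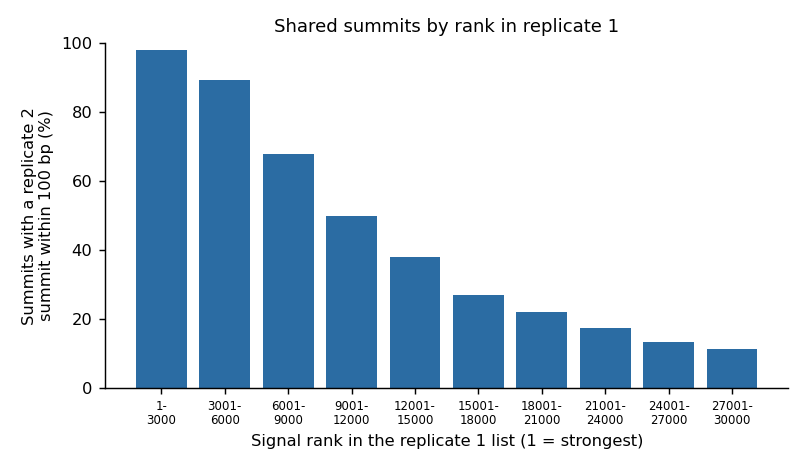
Bars give the share of replicate 1 summits, in groups of 3000 by signal rank, that have any replicate 2 summit within 100 bp; the x axis is the rank and the y axis the share in percent. The share falls from 97.8% in the strongest group to 11.4% in the weakest.

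The IDR peaks lay mostly in introns and at promoters and almost never in coding exons. Of 7645 summits, 3474 (45.4%) were in introns, 2460 (32.2%) within 500 bp of a start site and 1527 (19.97%) between genes. Promoters held 2.37 times the number given by random placement on the same arm (95% interval 2.28 to 2.47). Coding exons held 6 summits where 999.8 were expected (ratio 0.006, or 0.0265 with placement matched on AT content and 0.173 in the pooled list), and 3' untranslated regions (UTRs) 60 where 386.4 were expected (ratio 0.155, or 0.427 in the pooled list). The 6 summits in coding exons, named after their values were seen, were in bip1, Pde1c, sgg, su(w[a]), CG4080 and Ubr1.

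The other classes departed less from random placement. Introns held 1.15 times and intergenic sequence 0.734 times the expected number. Summits in 5' UTRs numbered 33 against 59.85, and those in other exons 85 against 62.51. Each class differed from random placement by a two-sided permutation test, with Benjamini-Hochberg adjusted p of 0.00599 for other exons and 0.00233 for the remaining classes. The raw p of those classes, 0.002, is the smallest that 1000 placements can give. In the top 7645 peaks of replicate 1 and of replicate 2, promoters held 33.3% and 32.7% and coding exons 0.0785% and 0.105%. With placement matched on AT content, chosen after seeing the data, introns were at 0.99 times and 5' UTRs at 0.782 times the expected number (exact Poisson test, adjusted p of 0.569 and 0.202). The 5' UTR deficit was also not past the threshold with promoters of 250 bp, and it turned to a ratio of 1.24 in the pooled list, while the excess in other exons was not past the threshold with promoters of 1000 bp (permutation test, adjusted p = 0.0979).

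**Figure D2:**
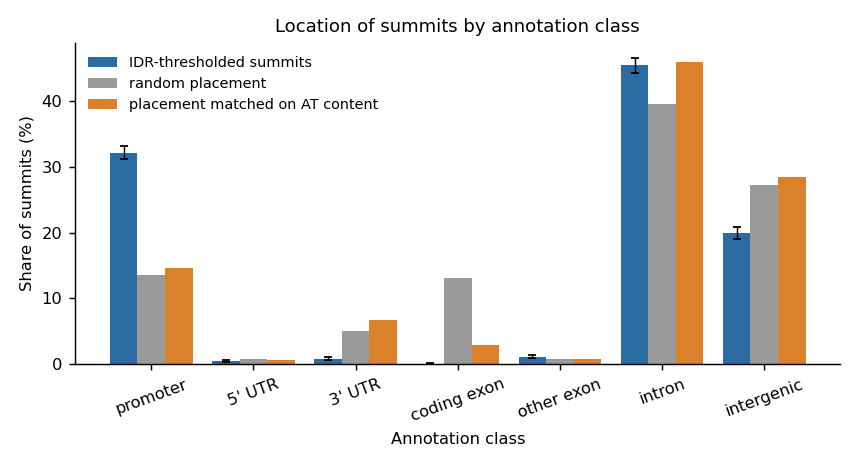
Bars give the share of 7645 IDR summits (with Wilson 95% intervals) in each annotation class, beside the shares under random placement and under placement matched on AT content; the y axis is in percent. Promoters hold 32.2% of summits against 13.6% and 14.7%, and coding exons 0.0785% against 13.1% and 2.96%.

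Promoter summits lay mostly upstream of the start site. Among 2236 summits within 500 bp of a protein-coding start site, the median position was 130 bp upstream, and 1777 (79.5%, Wilson 95% interval 77.7 to 81.1) were upstream. The 200 bp before the start site held 1129 of them.

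Chromosome 4 and the sequence near the centromeres held few peaks. Chromosome 4 had 16 IDR peaks, or 12.02 per Mb, with an odds ratio of 0.208 against the other arms by length (exact binomial test, adjusted p = 6.27e-16) and of 0.436 in the pooled list. Within 2 Mb of the centromeric ends of the 5 large arms there were 22 peaks, 10 on 2L and 12 on X, or 2.24 per Mb against 62.1 per Mb in the rest of these arms. Repeats there limit where reads can be placed, and mappability was not measured here. Arm 3L held 63.2 peaks per Mb (odds ratio 1.14, adjusted p = 7.49e-06) and 2R 50.8 (odds ratio 0.866, adjusted p = 5.76e-06) by the same exact test. The deficit on 2R was not past the threshold with an expectation matched on AT content, chosen after seeing the data (odds ratio 0.951, exact binomial test, adjusted p = 0.202). Arms 2L and 3R did not pass the test, with 58.6 and 54.9 peaks per Mb (exact binomial test, adjusted p of 0.336 and 0.0626). The 3R deficit did pass it in the pooled list and in the top peaks of replicate 1 (odds ratios 0.888 and 0.93, exact binomial test, adjusted p of 1.76e-17 and 0.0115).

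The X chromosome held 61.3 peaks per Mb (odds ratio 1.09, exact binomial test, adjusted p = 0.00676). This excess did not hold in the top 7645 peaks of replicate 1 alone (odds ratio 1.05) or with an expectation matched on AT content (1.04), and among the 1911 strongest IDR peaks the odds ratio was 0.912. The adjusted p of the exact test ranged from 1.4e-23 in the pooled list to 0.211 over the alternatives. The sex of the pupae is not given in the labels.

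Promoter peaks ranked somewhat higher than other peaks. In the IDR list split into 5 groups of 1529 by signal, 37.9% of the strongest group were at promoters (Wilson 95% interval 35.5 to 40.3), against 29.7% to 31.4% in the other groups. The mean rank was 3678 for promoter peaks and 3892 for other peaks (two-sided permutation test with 100000 resamples, p = 8e-05). The difference of 213.5 ranks was 358.0 in the top 7645 peaks of replicate 2 and 19.9 in those of replicate 1 (permutation test, p = 0.715), and the difference between the replicates was not tested. With promoters of 250 bp it was 119.2 (permutation test, p = 0.0461). Of the pooled peaks outside the IDR list, 27.6% were at promoters, a lower share than in the IDR list (Fisher's exact test, odds ratio 1.25, p = 1.85e-14). Coding exons held 3.01% of those weaker peaks. Their −log10 q goes down to 0.405, so some may not be binding sites, and these shares may reflect that.

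Genes for ribosomal proteins were bound more often than other genes, and genes for cuticle proteins and for chemosensory receptors less often. In all, 2713 of 13945 protein-coding genes (19.5%) had an IDR summit within 500 bp of a start site. Of the 86 cytoplasmic ribosomal protein genes, 43 were bound (50%, Wilson 95% interval 39.7 to 60.3; log2 odds ratio 2.07, Fisher's exact test, p = 1.81e-10, adjusted p = 2.26e-09). The bound genes with the highest signal were RpL34b, RpL32, RpS20 and RpS27, with summits 118 to 160 bp upstream of the start site, and RpL10 and RpL10Aa were not bound. Among the 1911 strongest IDR peaks the log2 odds ratio of this group was -1.12 (Fisher's exact test, adjusted p = 0.476).

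Of the mitochondrial ribosomal protein genes, 26 of 73 were bound (35.6%, log2 odds ratio 1.22, Fisher's exact test, p = 0.00152, adjusted p = 0.00949). They were led by mRpL41, mRpS10, mRpS23 and mRpL23, while mRpL1 and mRpL12 were not bound. The peak of mRpS23 is the one at the CenG1A promoter. This call was lost with each summit given only to its nearest start site (Fisher's exact test, adjusted p = 0.459), among the 1911 strongest peaks (0.476) and in the top peaks of replicate 1 (0.143). It was also lost with rotated peaks as the background (permutation test, adjusted p = 0.1998).

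Among 122 cuticle protein genes, 2 were bound, Cpr12A and Cpr72Ea (1.64%, log2 odds ratio -3.56, Fisher's exact test, p = 2.52e-09, adjusted p = 2.1e-08). Acp65Aa and Ccp84Aa were among those not bound. Among 179 genes for odorant, gustatory and ionotropic receptors, 1 was bound, Gr77a (0.559%, log2 odds ratio -4.87, Fisher's exact test, p = 7.3e-16, adjusted p = 1.83e-14), and Gr10a and Gr10b were not. In the top peaks of replicate 1 and of replicate 2, 1.64% and 0.820% of the cuticle genes were bound, and 0.559% of the receptor genes in each. With rotated peaks as the background, where the measure is the share of bound genes relative to all genes, the adjusted p was 0.04995 for the cuticle list and 0.025 for the receptor list (permutation test).

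The remaining lists did not pass Fisher's exact test. Of the chromatin and Polycomb or Trithorax genes, 11 of 27 were bound (Fisher's exact test, adjusted p = 0.0586), with the strongest peaks at ph-p and brm. Of the ecdysone response genes, 10 of 26 were bound (Fisher's exact test, adjusted p = 0.0815), with the strongest at the ecdysone-induced transporter gene E23 and the cell death gene hid. Glycolysis had 6 of 12 (Fisher's exact test, adjusted p = 0.0706), with Gapdh2 and Hex-A, and the circadian clock 5 of 10 (adjusted p = 0.0915), with sgg and cry. The glycolysis list passed Fisher's exact test in the top peaks of replicate 2 and of replicate 1 (adjusted p of 0.0189 and 0.0194), with nearest start sites only (0.0179) and among the 1911 strongest peaks (0.036), but not with other distances or the model with promoter AT content. With nearest start sites only, the chromatin, ecdysone response and circadian clock lists passed it too (Fisher's exact test, adjusted p of 0.0179, 0.0168 and 0.0331). The ecdysone response list also passed within 1000 bp and in the top peaks of replicate 1, but not in those of replicate 2 (Fisher's exact test, adjusted p of 0.0185, 0.0403 and 0.369), and the difference between the replicates was not tested. In the model with promoter AT content and start site clusters, neither the ecdysone response nor the circadian clock list passed. Their log2 odds ratios were 0.50 and 0.94 there, against 1.40 and 2.05 without the model (logistic model, adjusted p of 0.602 and 0.517). With rotated peaks as the background, the ecdysone response, circadian clock and glycolysis lists did not pass (permutation test, adjusted p of 0.831, 0.831 and 0.830). The zinc-finger list to which CG17806 belongs had 19 of 66 (Fisher's exact test, adjusted p = 0.170), with CG1792 and CG10147. It passed within 250 bp and in the top peaks of replicate 1 (Fisher's exact test, adjusted p of 0.0395 and 0.035), but not in the top peaks of replicate 2, within 1000 bp, with nearest start sites only or among the 1911 strongest peaks (Fisher's exact test, adjusted p from 0.306 to 1). None of the 12 Hox cluster genes was bound (Wilson 95% upper limit 24.2%, Fisher's exact test, adjusted p = 0.250). In the top peaks of replicate 2, however, 16.7% of them were bound (log2 odds ratio -0.12 in place of -2.60).

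Replication and cell cycle genes were bound in 9 of 26 cases (Dp and RnrS strongest, Fisher's exact test, adjusted p = 0.192), and insulator and promoter architecture genes in 6 of 17 (Chro and Cp190, adjusted p = 0.231). The latter list passed in the top peaks of replicate 2, with 52.9% bound (Fisher's exact test, adjusted p = 0.0155), and had 41.2% bound in those of replicate 1. Oxidative phosphorylation had 17 of 84 (ND-ASHI and ND-MWFE, Fisher's exact test, adjusted p = 0.967), the proteasome 6 of 32 (Rpn3 and Rpn5, adjusted p = 1) and heat shock 4 of 18 (Hsp27 and Hsp26, adjusted p = 0.870). Innate immunity had 6 of 23 (cact and imd, Fisher's exact test, adjusted p = 0.670), patterning and imaginal disc genes 4 of 42 (ct and salr, adjusted p = 0.231) and ecdysone synthesis 1 of 11 (shd, adjusted p = 0.849).

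Among the cell type lists, glia had 4 of 10 (moody and nrv1, Fisher's exact test, adjusted p = 0.231), fat body 5 of 13 (bmm and foxo, adjusted p = 0.250) and germline 3 of 12 (bgcn and vas, adjusted p = 0.849). Muscle had 3 of 24 (sls and Tm1, Fisher's exact test, adjusted p = 0.795), neuron 3 of 24 (elav and Rbp9, adjusted p = 0.795), trachea and gut 2 of 10 (trh and dysf, adjusted p = 1) and blood cells 1 of 13 (crq, adjusted p = 0.713). With lists this short the intervals are wide, as the plot of bound genes per list shows.

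**Figure D3:**
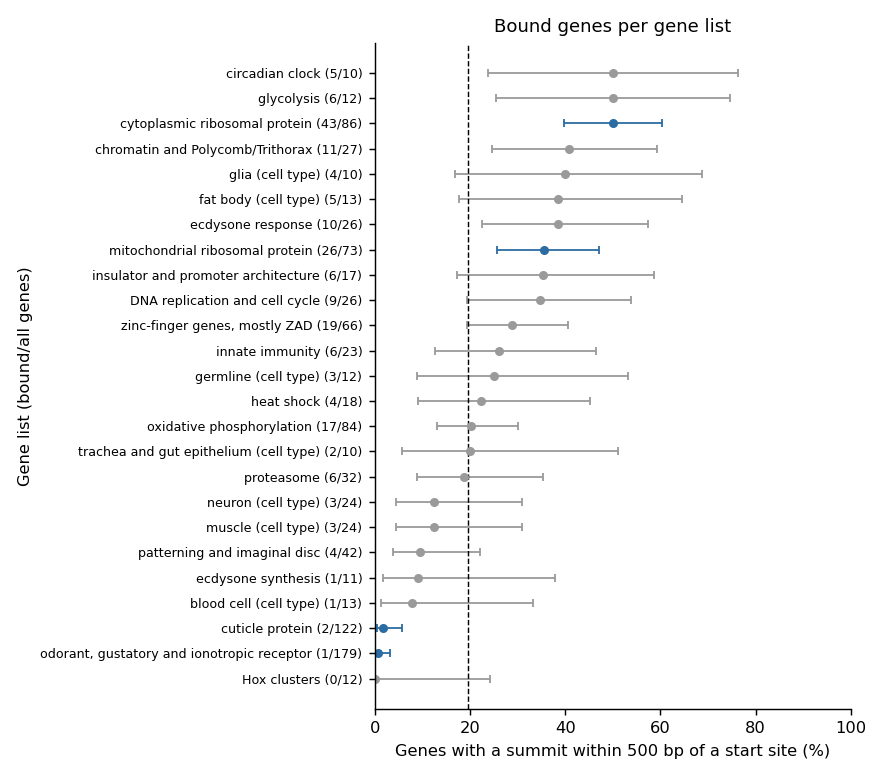
Points give the percentage of each list's genes with an IDR summit within 500 bp of a start site, with Wilson 95% intervals; blue marks the 4 lists that passed the test, and the dashed line is the share over all protein-coding genes, 19.5%. The cytoplasmic ribosomal protein list stands at 50% and the receptor list at 0.559%.

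Summits lay in short stretches rich in A and T. Within 50 bp of the summit, 68.9% of bases were A or T (SD 8.14 across 7645 peaks), against 54.5% (SD 8.28) around 250 bp away and 57.8% in the genome. The centre was richer than the flanks in 6663 peaks (87.2%). The value was 68.3% in the top peaks of replicate 1 and 68.9% in those of replicate 2, and went from 71.0% in the strongest group of 1529 IDR peaks to 66.5% in the weakest. In the 22355 pooled peaks outside the IDR list it was 59.8%. The −log10 q of these peaks goes down to 0.405, so some may not be binding sites.

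**Figure D4:**
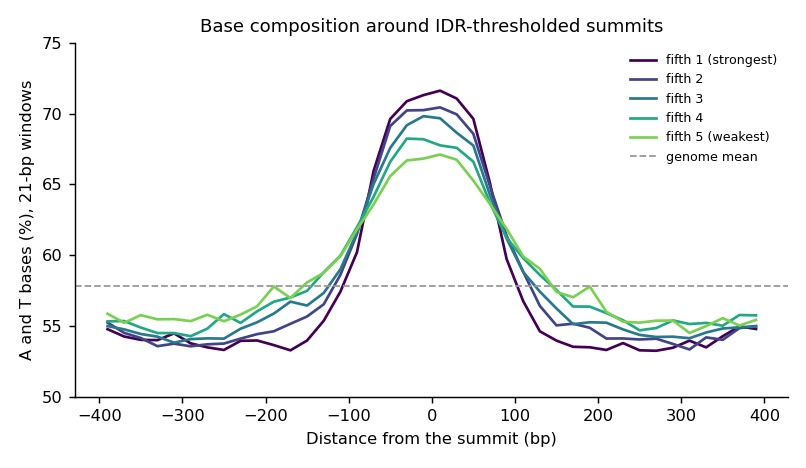
Lines give the percentage of A and T bases in 21-bp windows by distance from the summit in bp, for the IDR peaks in 5 groups of 1529 by signal; the dashed line is the genome mean, 57.8%. Within 50 bp of the summit the strongest group averages 71.0% and the weakest 66.5%.

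The TATA box was found near the summit in 26.2% of peaks and in the flanks in 9.51% (exact sign test, adjusted p = 9.09e-156), runs of A or T in 10.99% and 6.67% (adjusted p = 5.76e-21), and the Su(Hw) core in 0.419% and 0.131% (adjusted p = 0.00212). Of 18 motifs these 3 were more frequent at summits. The 7 less frequent ones were GAGA, the CA repeat, the E-box, the CTCF core, Pho, the Initiator and the Ftz-f1 motif, with Pho at 11.4% against 20.4% (exact sign test, adjusted p = 5.86e-51) and GAGA at 1.203% against 3.58% (adjusted p = 6.07e-22). DRE, the BEAF-32 site, Motif 1, Zelda, the EcR/Usp palindrome, the nuclear receptor site and both random control words did not pass the test. The Initiator call was lost with 100 bp to each side, among the 1911 strongest peaks, in peaks outside promoters and in the top peaks of either replicate (exact sign test, adjusted p from 0.0762 to 0.551). The Ftz-f1 call, which rests on 1 peak against 10, was lost among the strongest peaks, in promoter and in other peaks taken apart and in the top peaks of replicate 2 (exact sign test, adjusted p from 0.0639 to 1). In promoter peaks alone the Su(Hw) core and the E-box did not pass the test either (exact sign test, adjusted p of 0.158 and 0.211). The TATA box was counted as TATAAA on either strand at any place in the window, not at a set distance from a start site. Its excess over the flanks was 14.1 percentage points in promoter peaks and 17.9 in other peaks. With 100 bp to each side DRE and Motif 1 were higher and Zelda lower at summits (exact sign test, adjusted p of 2.06e-07, 0.0163 and 0.0169), and DRE was also higher in the top peaks of replicate 2 and Motif 1 in peaks outside promoters (exact sign test, adjusted p of 0.00465 and 0.0212). DRE did not pass in the top peaks of replicate 1 or among the 1911 strongest, nor Motif 1 in the top peaks of replicate 2 (exact sign test, adjusted p of 0.471, 0.263 and 1).

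Against windows of equal AT content and annotation class without a peak, a comparison chosen after seeing the data, the TATA box was no more frequent at summits (26.2% and 26.4%, Fisher's exact test, adjusted p = 0.845). The Su(Hw) core had an adjusted p of 0.0793 by Fisher's exact test there, runs of A or T 0.801 and the E-box 0.801. Pho was the 1 motif still lower at summits, at 11.4% against 13.02% (Fisher's exact test, adjusted p = 1.04e-04). GAGA, lower at summits than in the flanks, was higher than in these windows (1.203% and 0.657%, Fisher's exact test, adjusted p = 2.14e-06), and Motif 1 was higher too (0.536% and 0.162%, adjusted p = 8.91e-09).

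Of all 8192 words of 7 bases, the 3 that stood out most in the 2662 peaks of chromosome 2 were AAAATAT, TTTAAAA and AAATATT. In the 4983 peaks of the other chromosomes they were found near the summit in 19.02%, 16.6% and 15.7% of peaks and in the flanks in 5.82%, 4.44% and 4.54% (exact sign test, adjusted p of 1.52e-86, 1.08e-84 and 1.09e-73). All 64 words made only of A and T were more frequent at summits.

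The neighbourhood of CG17806 held more peaks than most of the genome, and the IDR peak at the gene itself was not among the strongest. Within 20 kb of the gene there were 34 peaks in replicate 1, 24 in replicate 2, 31 in the pooled list and 8 in the IDR list. Random windows of the same 41.7 kb had means of 9.33, 9.37, 9.35 and 2.41, and as many peaks were found in 2.43%, 3.98%, 3.72% and 7.13% of 9997 such windows. The IDR peak at the CG17806 promoter spans 3R from 17803122 to 17803497, has its summit 50 bp upstream of the start site and ranks 4963 of 7645. The IDR peak of highest signal in the window ranks 828, at 17794462 to 17794810, with its summit between the start sites of CG43102 and pasi1. Replicate 2 has no summit over the gene or its promoter.

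**Figure D5:**
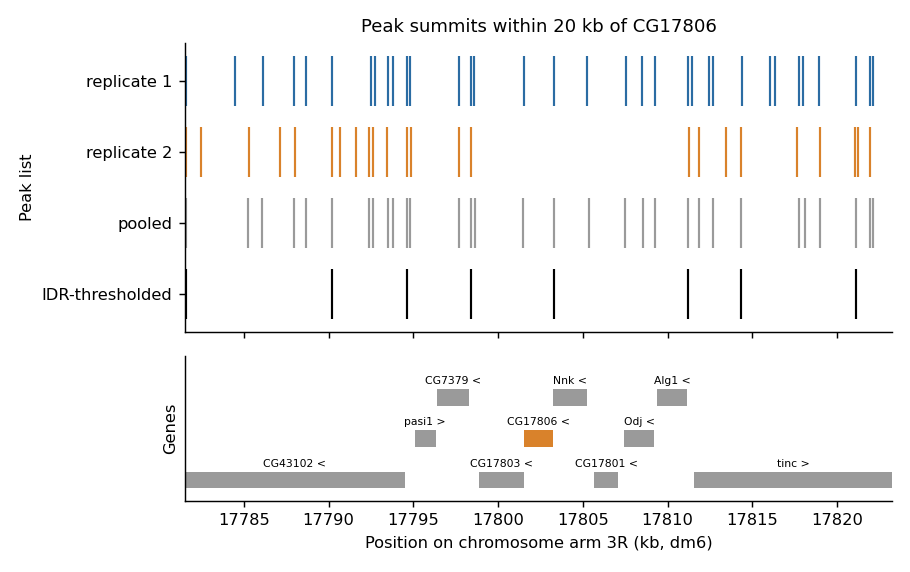
Vertical lines mark peak summits of the 4 lists along chromosome arm 3R (kb, dm6) within 20 kb of CG17806, and bars mark the genes, with arrows for the strand. The pooled list has 31 summits and the IDR list 8, and replicate 2 has none over the CG17806 gene.

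For none of the 4 kinds of small RNA gene did the number bound pass the test against rotated peaks. An IDR summit lay within 500 bp of 27 of 290 tRNA genes against a mean of 16.5 (permutation test, two-sided, p = 0.104, adjusted p = 0.416), of 3 of 32 snRNA genes against 2.01 (adjusted p = 0.627), of 8 of 269 snoRNA genes against 15.7 (adjusted p = 0.539) and of none of 99 rRNA genes against 5.55 (adjusted p = 0.627). For tRNA genes the replicates went different ways. The ratio to the rotations was 2.49 in the top peaks of replicate 1 (permutation test, adjusted p = 0.00799) and 0.735 in those of replicate 2 (adjusted p = 0.687), and the difference between them was not tested. For the few snRNA genes the ratios were 2.48 and 0.494 in the same order (permutation test, adjusted p of 0.312 and 0.845).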

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

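The settings matched on AT content, the model with promoter AT content and the lists without chromosome 4 were chosen after seeing the data, and the others before. Several results kept their direction and their side of the threshold under every alternative run. These were agreement between replicates, the excess at promoters, the deficits in coding exons and on chromosome 4, and the 2 lists with fewer bound genes. Agreement ranged from 43.5% over all peaks to 82.4% for the top 1000. The top 3 words of each setting, which can be other words, were all higher at summits than in the flanks. The X chromosome odds ratio was 0.912 among the 1911 strongest IDR peaks and 1.04 with an expectation matched on AT content, neither past the threshold, and 1.05 to 1.11 with a replicate left out, the lower value without replicate 2. The rank difference of promoter peaks was 19.9 to 358.0 with a replicate left out. The number of lists with more bound genes was 5 with nearest start sites only, 1 among the 1911 strongest peaks (glycolysis), 1 with rotations (cytoplasmic ribosomal proteins) and 4 with either replicate left out. The cytoplasmic ribosomal protein list had a log2 odds ratio of -1.12 among the 1911 strongest peaks. The number of motifs higher at summits was 5 with 100 bp to each side and 3 to 5 with a replicate left out, where 1 of the random control words passed without replicate 1; the number lower was 1 against AT-matched windows. In that comparison the differences in percentage points were 0.546 for GAGA, 0.0196 for the CA repeat, 0.154 for the CTCF core, -0.204 for the TATA box and 0.138 for the Initiator. The tRNA ratio was 0.735 to 2.49 and the snRNA ratio 0.494 to 2.48 with a replicate left out. The 5' UTR ratio was 1.24 in the pooled list, and the intron ratio 0.99 with AT-matched placement. Apart from the AT-matched settings, whose construction removes composition, the cause was not tested. Ranking by q-value gave no value, since all IDR peaks share 1 q-value. No paired analysis was possible because there is 1 group. Depth is unknown, so how it limits the weaker peaks cannot be given.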

Other observations

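The tests in this part were chosen after the peaks had been examined; the bounds for the AT words and for the gene list model were written before their results were seen, and those of the other tests after. The cytoplasmic ribosomal protein genes were bound often but by weaker peaks. Their 43 bound members had a median IDR rank of 5032 against 3459 for all 2713 bound genes (permutation test of mean rank, two-sided, p = 2e-05, the smallest 100000 resamples can give; adjusted p = 0.00012 over the 6 lists with at least 10 bound genes). For the mitochondrial ribosomal protein genes a difference did not pass the test (median rank 3604.5, permutation test, adjusted p = 0.869). The 10 bound ecdysone response genes had a median rank of 2105 (permutation test, p = 0.0434, adjusted p = 0.130). Each gene was given its strongest peak, so genes with more start sites can reach higher ranks, and this was not matched. Over all list members, the mean number of start site clusters was 2.19 for ecdysone response, 1.05 for cytoplasmic and 1 for mitochondrial ribosomal protein genes.

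Summits were clustered along the arms, with a median gap of 4895 bp against 12018 bp for uniform draws, and some long genes held many. The cell adhesion gene kirre (X from 2740384 to 3134532) held 35, Tet 26, SKIP 24, and CG43658 and Snoo 23 each. The counts are not scaled by gene length: kirre, of 394.1 kb, had 0.0888 summits per kb against 0.28 for Tet and 0.343 for shn, which held 20. The ecdysone-induced nuclear receptor gene Eip75B held 17, or 0.149 per kb, and several genes not named here held more. The genes given were named after their values were seen.

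Summits were AT-rich, but at like AT content the classes differed. Of the windows with at least 70 and under 80 AT bases, 4.02% in promoters, 1.86% in introns and 1.35% between genes were within 50 bp of an IDR summit. In coding exons the share was 0.0617% and in 3' UTRs 0.124%. That most windows lay away from a summit follows from the number of peaks, so only the contrast between classes counts here. With placement matched on AT content, coding exons still held 0.0265 of the expected number (95% interval 0.00974 to 0.0578) and promoters 2.19 times, which argues against base composition alone. The top 3 AT words were nearly as frequent in matched windows without a peak, with a median ratio of 1.07 (bootstrap 95% interval 1.02 to 1.12), and upper limits of 1.12 to 1.17 for the 3 words stayed below the bound written beforehand, which argues against these 3 words as the main source; with 1 window per peak this outcome had changed from draw to draw, and 20 were used after that was seen. Smaller differences stay open, since 6 of the 64 AT words were higher than in matched windows, TTTAAAA (ratio 1.095) among them and AATATTA highest (1.16, upper limit 1.26), and 7 were lower, TAATTAA lowest (0.823). An AT preference of the library may remain, since the control reads were not analysed here, and no biological explanation was tested, as the design has 1 group.

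The excess of peaks around CG17806 was weighed against its surroundings. From AT content and annotation class, 11.9 pooled peaks were expected and 31 were found, a ratio of 2.60 with a Poisson interval of 1.77 to 3.69, which on its own would have set the locus apart. Because peaks cluster, that test was replaced after its result was seen by a comparison with 2009 random windows of like expectation (within 10%), of which 8.56% held as many (mean 13.9, SD 10.7). Composition and gene density thus predict fewer peaks than were found, but windows alike in these vary so widely that a count of 31 is not rare among them. By these counts, extra copies of the locus in the transgenic line cannot be told apart from this spread: in the replicates 5.63% and 8.77% of such windows held as many peaks. In 10-kb bins from the middle of the gene, replicate 1 had peaks out to 30 kb on both sides and none from 30 to 80 kb. Replicate 2 had some from 30 to 80 kb on both sides and none over the gene or its promoter. The extent of any extra copy is not known here, so these positions do not decide it. No biological explanation was tested.

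The differences between gene lists were set against promoter composition and the number of start sites. In a logistic model with both, the called list nearest to 0 was that of mitochondrial ribosomal proteins, with a log2 odds ratio of 1.42 (95% interval 0.71 to 2.14). In this model these properties alone thus do not account for the 4 calls. The model treats genes as independent and has no term for a peak shared by neighbouring genes. The mitochondrial call itself was lost with nearest start sites only (Fisher's exact test, adjusted p = 0.459) and with rotated peaks (permutation test, adjusted p = 0.1998). In the same model the chromatin and Polycomb or Trithorax list passed the threshold (log2 odds ratio 1.81, 95% interval 0.65 to 2.98). It did not pass Fisher's exact test (adjusted p = 0.0586) or the permutation test with rotated peaks (adjusted p = 0.741). Gene expression was not analysed here, and no biological explanation was tested.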
